A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

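The series holds 8 arrays, each with 2 colours, of Halobacterium salinarum NRC-1, a halophilic archaeon, in a strain from which the ura3 and phr1 genes were removed. Per the labels, 50 mL cultures grew in 125 mL flasks at 210 or 100 rpm, which sets high or low oxygen, in light or in dark. Total RNA of each of the 4 combinations was hybridised against a standard reference RNA of mid-log NRC-1 cells (optical density 0.5 to 0.6 at 600 nm). The series describes 4 samples in duplicate as dye-flips, which was read as 1 RNA sample per combination on 2 arrays, with the sample in Alexa 532 on replicate 1 and in Alexa 647 on replicate 2. The 2 arrays of an RNA sample were therefore taken as 1 replicate.

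The deposited scanner tables give spot and background brightness as raw intensity, per the file headers, at a high and a low gain for each dye, with the spread of the background in the same intensity unit. A spot confidence in percent is given per scan, per the file headers, and it was low on saturated spots. The deposited series matrix holds log10 ratios that the authors computed, a scale found from the numbers. Its values lay within 0.001 of the log10 ratio of Alexa 532 over Alexa 647 plus 1 constant per array for 83.3% to 93.1% of the spots that hold a value, with constants of 0.106 to 0.467. No background was subtracted in them, and all 8 columns run in the same dye direction, so the authors' table does not turn the flipped arrays. Its medians were 0.166 and 0.0924 in high_oxygen_light, 0.117 and 0.0973 in high_oxygen_dark, 0.0700 and 0.102 in low_oxygen_light and 0.0701 and 0.1000 in low_oxygen_dark, for replicates 1 and 2, and the origin of the constants stays unknown. The table leaves 16.1% of the spots of tested probes blank, the same ones on all 6 arrays of the first number series, and 0 on the 2 of the second, which are both in dark, so its blanks are not balanced over light. The quantification software, the array design and the labelling chemistry are not given in the sources used here.

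Each array has 10752 spots. The layout repeats every probe on 4 spots, which gives 2688 probes, of which 288 are empty positions and 2400 were tested. The platform annotation gives 1 gene symbol for 133 of the 2400 probes (5.54%), several for 0 and none for 2267. Probes without a symbol are unnamed here and are given by the ID of their first spot, and that does not mean that they lack a gene. The annotation table on hand describes another strain with other identifiers and was not used here for names or positions.

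Ratios were computed with limma 3.58.1 in R 4.3.3. The mean of the high-gain scan was used, and spots saturated there took their value from the low-gain scan through a line fitted to unsaturated spots between 10000 and 40000 (correlation 0.974 to 0.996). Between 137 and 679 spots per array were saturated in Alexa 532 and between 537 and 1199 in Alexa 647. Background was corrected with normexp and an offset of 50, and log ratios were normalised within each array by loess with a span of 0.3, with empty positions at weight 0. The ratio was turned to sample over reference from the dyes in the labels, the 4 spots of a probe were averaged, and then the 2 arrays of each RNA sample. A spot was taken as above background when its net brightness passed the 95th percentile of the empty positions of its array and channel (quantile 0.95), and a probe when at least 3 of its 4 spots did.

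Signal limits the precision of these arrays. The median spot read 2.09 to 4.57 times its background in Alexa 532 and 2.14 to 9.16 times in Alexa 647, against 1.08 to 1.32 times for empty positions. Of the 2400 probes, 976 (40.7%) were above background in both channels on all 8 arrays, 88 of them with a symbol. Between 1605 and 2112 probes per array were above background in the sample channel. No pair of the 28 array pairs had identical spot means.

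Oxygen (low minus high) and light (light minus dark) were fitted together in limma over the 4 RNA samples, with lmFit and eBayes and Benjamini-Hochberg adjustment at a threshold of 0.05. The 2 by 2 layout leaves 1 residual degree of freedom per probe, the oxygen-by-light contrast, and the moderated test had 3.53. The p-values measure only the spread between these 4 RNA samples, with no second culture of any combination. Gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated. With 1 residual degree of freedom per probe, that estimate depends only on the signs of the residuals, so it is no separate check. Before the data were examined, 19 lists, the comparisons, the alternatives and the rule for named genes were fixed. With at least 3 named genes required, 7 of these lists were tested, 8 had 1 or 2 named genes, and 4 had none. The lists tested were other rhodopsins, TCA cycle, DNA repair, cobalamin and heme synthesis, chaperones and proteases, flagella and chemotaxis, and pyrimidine and purine synthesis. The interaction, the ratios to the reference, the targeted genes and the split of the variance are values with no test.

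The rule for named genes took genes past the threshold whose change had the same sign in the 4 differences between arrays of the same orientation. Where fewer than 5 passed in a direction, it took the largest changes with that sign pattern up to 5, as values and not as calls. It also took up to 4 members of each list by smallest p, the targeted genes, the 4 largest interactions in each direction, and the 5 highest and 5 lowest named genes against the reference. Most probes lack a symbol, so the same filling was also done among probes with a symbol, which was chosen after the names were seen.

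The array numbers fall into a first series (4788 to 4795, 6 arrays) and a second (5958 and 5959, both in dark with the sample in Alexa 532). The series was treated as a batch, as a term in a fit of the 8 arrays with dye and with the RNA sample as a random block, and by values within each series. The alternatives covered background correction, offset, normalisation within and between arrays, a filter on dim probes, the high-gain scan alone, the median over spots, the authors' table, either dye orientation, leaving out each array, the unit of replication, the covariate and the eBayes prior. Loess within each sub-grid, the 6 arrays of the first series alone, the authors' table from spots blank on no array, the lists without pyrF, adjustment over named probes alone and 5 further lists were added after the data were seen.

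The procedure was tested on simulated data of the same layout, with 2400 probes of which 200 changed, in 20 runs. It recovered 23.4% of the probes with a 1.5-fold change, 83.4% with a 2-fold and 97.6% with a 4-fold change, with 8.9 false calls per run. An array-level fit recovered 91.6%, 98.7% and 99.8%, with 99.0 false calls per run. In the simulation the dye term cancels and the noise of single arrays is small, so both orientations give similar changes. In the real data the oxygen changes of the orientations had a correlation of 0.02. The array-level rates therefore need not hold for these arrays. The rates of the reported fit are for 200 changed probes, and so many true changes ease the Benjamini-Hochberg threshold. They need not hold where fewer probes change. In the real data the lowest unadjusted p for oxygen in limma was 0.00242, with an adjusted p of 0.706. For a simulated list of 9 genes, camera gave p under 0.05 in 20 of 20 runs with a shift of 0.5 and in 0 of 20 with none. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.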

Results

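RNA abundance was measured in a knockout strain of Halobacterium salinarum NRC-1 lacking ura3 and phr1. The ura3 gene, annotated as pyrF, encodes orotidine 5'-phosphate decarboxylase of pyrimidine synthesis, and phr1 belongs to the photolyase family. Each of 4 combinations (high_oxygen_light, high_oxygen_dark, low_oxygen_light, low_oxygen_dark) gave 1 RNA sample on 2 dye-flip arrays, so each oxygen level and each light state had 2 RNA samples. By the title of the series, the comparisons ask how this strain responds to oxygen and light. Only 133 of the 2400 probes carry a gene symbol, so neither phr1 nor phr2 could be found, and genomic positions were not analysed here. Values are log2 ratios.

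Low against high oxygen left no gene past the test. Among genes with a symbol and the same sign in every difference between arrays, purL had the largest value. This gene encodes phosphoribosylformylglycinamidine synthase of purine synthesis, and it was 0.45 ± 0.09 higher at low oxygen (SE, 2 RNA samples per level, adjusted p = 0.706). Its 4 differences between single arrays were 0.47 and 0.50 in light and 0.41 and 0.42 in dark. Of the 19 named genes with the same sign in all 4 differences, the other largest with higher values were glpK (glycerol kinase, 0.30 ± 0.09), sucC (a subunit of succinyl-CoA synthetase, 0.30 ± 0.09), gdhA2 (a glutamate dehydrogenase, 0.29 ± 0.12) and rpl12p (a protein of the large ribosomal subunit, 0.28 ± 0.09). The 5 largest with lower values were cca (the enzyme that adds the CCA end to tRNA, -0.23 ± 0.10), hop (the light-driven chloride pump halorhodopsin, -0.22 ± 0.09), nuoL (a subunit of NADH dehydrogenase, -0.15 ± 0.09), msrA (methionine sulfoxide reductase, -0.15 ± 0.09) and csg (the cell surface glycoprotein, -0.14 ± 0.09). When each array was left out in turn, the values ranged from 0.40 to 0.49 for purL, 0.15 to 0.46 for glpK, 0.12 to 0.47 for sucC, 0.17 to 0.41 for gdhA2 and 0.11 to 0.45 for rpl12p. They ranged from -0.48 to 0.02 for cca, -0.32 to -0.11 for hop, -0.25 to -0.05 for nuoL, -0.29 to -0.02 for msrA and -0.22 to -0.06 for csg. Over all alternative settings the gdhA2 value ranged from -0.10 to 0.60 and was above 0 under 25 of 27.

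In limma, 0 of 2400 probes had an adjusted p under 0.05 for oxygen (lowest 0.706), and 161 had an unadjusted p under 0.05, 80 higher and 81 lower at low oxygen, against 120 by chance. The array-level fit with dye and the RNA sample as a random block called 11 probes, 7 higher and 4 lower. The only one with a symbol was purL (adjusted p = 0.0422). The consensus correlation within RNA samples in this fit was -0.41. A value below 0 makes the error of an oxygen change smaller than independent arrays would give. The block is therefore no safeguard here against counting arrays as replicates. With the array number series as a further term this fit called 0, with a consensus correlation of -0.32. Adjusted over the 133 probes with a symbol alone, 0 passed (lowest 0.627), and the 6 arrays of the first series alone gave 0. Oxygen is balanced over the number series, so that term left the purL value at 0.45. Within the first series purL was 0.46, and in the second, with 1 array per level, 0.41. The second value is the dark Alexa 532 difference given above, and the first comes from the other differences. Their shared sign is thus fixed by the choice of purL. For oxygen, 61 probes were called with median centring (6 higher and 55 lower), 19 with the values of the authors (5 and 14) and 62 with loess within sub-grids (25 and 37), which was chosen after the data were seen. The purL gene was among the calls with median centring and within sub-grids and not among those with the values of the authors. Of the 11 probes of the array-level fit, 9, 4 and 10 were among these calls. Over all probes, 377 (15.7%) had the same sign in all 4 oxygen differences. Independent differences would give 12.5%, and these share RNA samples and 1 reference RNA. The largest such changes of any probe were in unnamed ones: probe_4845 (0.79), probe_4813 (0.71), probe_4195 (0.64), probe_863 (0.58) and probe_3453 (0.58) had higher values, and probe_749 (-1.0), probe_1335 (-0.95), probe_3405 (-0.74), probe_4409 (-0.74) and probe_2621 (-0.68) lower ones. These 5 lower probes were not well above background in the sample channel on any array, and probe_863 was so on 1 array, so their values are no measured folds.

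None of the 7 tested gene lists passed for oxygen (camera, lowest adjusted p = 0.991, or 0.996 with an estimated correlation). The estimated correlations, such as 1 for chaperones and proteases and -0.33 for DNA repair, reflect only residual signs and add no evidence. Of their members, 0 passed over all probes and 0 adjusted over the list alone. In pyrimidine and purine synthesis 5 of 9 genes were higher at low oxygen (mean 0.07), with purL at 0.45, purM at 0.13, pyrF at 0.08 and pyrB at 0.06. The pyrF gene is removed by the labels and its probe is dim, and without it, a choice made after the data were seen, 4 of 8 were higher (mean 0.07). The lowest p in this list adjusted over the list alone was 0.0834. In the TCA cycle 3 of 6 were higher (mean 0.02, median -0.02), with sucC at 0.30, icd (isocitrate dehydrogenase) at 0.10, citZ (citrate synthase) at -0.07 and mdh (malate dehydrogenase) at -0.15. The sensory rhodopsin and halorhodopsin list had 3 of 5 higher, with a mean of -0.03 and a median of 0.02. Its members hop, htr1, sop1 and htr2 were at -0.22, -0.11, 0.09 and 0.05. In DNA repair 2 of 4 were higher, with the mismatch repair gene mutL at -0.45 ± 0.11, the excision repair gene uvrA at 0.23, radB at -0.12 and uvrB at 0.04. The mutL value came from the first number series (-0.62), and that of the second was 0.07. Loess within sub-grids called mutL.

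The cobalamin and heme synthesis list had 3 of 6 members higher at low oxygen (mean -0.01), with hemA at 0.13, cbiG at -0.09, cobN at -0.08 and cbiQ at 0.05. Of chaperones and proteases 1 of 4 was higher (mean -0.06), with dnaK at -0.08, dnaJ at -0.08, the proteasome subunit genes psmB at -0.09 and psmA at 0.01. In flagella and chemotaxis 5 of 11 were higher (median -0.03, with a mean of 4.6e-04 and a camera direction of lower), with htr7 at 0.20, cheR at -0.16, htr8 at -0.15 and htr4 at 0.12. With the number series as a term the list means for oxygen were the same. Within the first and the second series they were -0.02 and -0.06 for the rhodopsins, 0.03 and -0.02 for the TCA cycle, -0.13 and 0.09 for DNA repair, and -0.01 and -0.01 for cobalamin and heme. They were -0.08 and -0.02 for chaperones and proteases, 0.0029 and -0.01 for flagella and chemotaxis, and 0.06 and 0.10 for pyrimidines and purines. Lists with under 3 named genes were not tested: bat, the regulator of the bacteriorhodopsin gene, was at 0.16, arcA (arginine deiminase) at 0.11, arcC (carbamate kinase) at -0.08, moaA at 0.03, moaC at 0.0011, nuoL at -0.15, rpl12p at 0.28, msrA at -0.15, dpsA at 0.01 and phoU at -0.0013. Gas vesicle, terminal oxidase, ATP synthase and general transcription factor genes have no symbol among these probes.

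**Figure D1:**
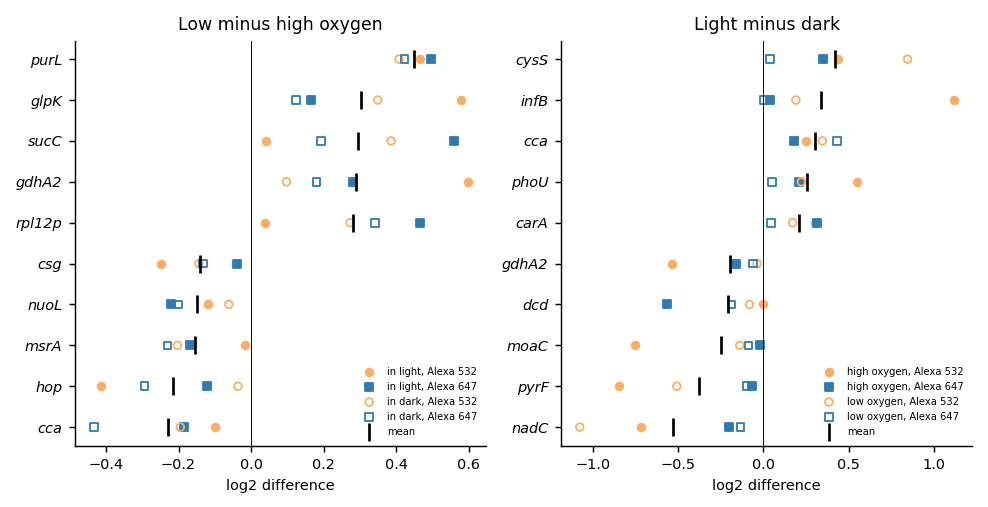
Differences in log2 ratio between single arrays (x axis) for the 5 named genes in each direction (y axis) with the largest mean and the same sign in all 4 differences, for oxygen (left) and light (right), with circles for arrays with the sample in Alexa 532, squares for Alexa 647 and black bars for the mean. The 4 oxygen differences of purL lie between 0.41 and 0.50, while those of infB for light lie between 0.0021 and 1.12.

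Light against dark also left no gene past the test. Of the 20 named genes with the same sign in all 4 differences, the 5 largest with higher values in light were cysS (cysteinyl-tRNA synthetase, 0.42 ± 0.09, adjusted p = 0.528), infB (a translation initiation factor, 0.34 ± 0.15), cca (0.30 ± 0.10), phoU (a regulator of phosphate uptake, 0.26 ± 0.11) and carA (a subunit of carbamoyl phosphate synthetase, 0.21 ± 0.10). The 5 largest with lower values were nadC (an enzyme of NAD synthesis, -0.53 ± 0.09), pyrF (-0.38 ± 0.09), moaC (molybdopterin synthesis, -0.25 ± 0.11), dcd (dCTP deaminase, -0.21 ± 0.09) and gdhA2 (-0.20 ± 0.12), with SE and 2 RNA samples per light state. The signals of the pyrF and nadC probes were not well above background on any of the 4 light arrays, and were above it on 3 and 2 of the 4 dark arrays, so their values are no measured folds. The cysS probe was above background on 3 light and 2 dark arrays, and its value was 0.21 with no background correction and 0.63 with plain subtraction. When each array was left out in turn, the values ranged from 0.13 to 0.71 for cysS, 0.10 to 0.57 for infB, 0.05 to 0.55 for cca, 0.05 to 0.47 for phoU and 0.14 to 0.27 for carA. They ranged from -0.86 to -0.21 for nadC, -0.58 to -0.18 for pyrF, -0.34 to -0.16 for moaC, -0.34 to -0.08 for dcd and -0.32 to -0.08 for gdhA2. The dcd probe was above background on 2 light and 4 dark arrays. For pyrF, 2 of these 3 dark arrays are those of the second number series. By the labels pyrF is removed from this strain, so the signal of its probe cannot be taken as its transcript.

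In limma, 0 of 2400 probes had an adjusted p under 0.05 for light (lowest 0.528), and 211 had an unadjusted p under 0.05, 122 higher and 89 lower in light, against 120 by chance. The array-level fit called 0, and it called 0 with the number series as a term. Adjusted over the probes with a symbol alone, 0 passed (lowest 0.397), and the first series alone gave 0. For light, 38 probes were called with median centring (20 higher and 18 lower), 58 with the values of the authors (50 and 8) and 62 with loess within sub-grids (38 and 24). The authors' table called dnaK (0.69) and phoU (0.78) higher and moaA (-0.46) lower, where moaA was at 0.06 here. That table leaves 2 of the 4 spots of dnaK and moaA and 3 of those of phoU blank on the first number series alone. From spots blank on no array, a choice made after the data were seen, it called 47 (44 higher and 3 lower), with dnaK at 0.69 and phoU at 0.75, and moaA (-0.38) was no longer called. Loess within sub-grids called pyrF lower. Light is not balanced over the number series, since both arrays of the second are dark. With the series as a term and within the first series, the cysS value was 0.19, cca 0.31, phoU 0.13, carA 0.18, infB 0.02, nadC -0.17, pyrF -0.08, moaC -0.06, dcd -0.38 and gdhA2 -0.11. The second series has no light array and gives no value. For light, the values with the series term and within the first series equal those of the Alexa 647 arrays alone. They are therefore 1 estimate and not separate checks. Both dark arrays with the sample in Alexa 532 are those of the second series. Number series and dye orientation thus cannot be told apart for light. The same sign in all 4 light differences was found for 350 probes (14.6%), where independent differences would give 12.5%. The largest of these were unnamed: probe_4839 (0.77), probe_755 (0.66), probe_405 (0.64), probe_663 (0.62) and probe_4771 (0.58) were higher in light, and probe_2589 (-1.05), probe_2577 (-0.84), probe_1575 (-0.81), probe_2775 (-0.75) and probe_4257 (-0.70) lower. Of these 10, only probe_405, probe_663 and probe_4771 were above background on some arrays.

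None of the 7 lists passed for light (camera, lowest adjusted p = 0.988, or 0.993 with an estimated correlation), and 0 members passed over all probes or adjusted over the list alone. Camera made no call at the preset correlation in either comparison, so none could be lost with an estimated one. All 4 chaperone and protease genes had higher values in light (mean 0.12), with dnaK at 0.24, psmA at 0.11, psmB at 0.10 and dnaJ at 0.04. The dnaK value was 0.01 without high_oxygen_light replicate 1 and 0.06 with the number series as a term. This list mean was above 0 under 17 of 18 alternatives and turned below 0 without the same array. In flagella and chemotaxis 9 of 11 genes had lower values in light (mean -0.03), among them htr7 (-0.18), htr6 (-0.16) and cheA (-0.12), while the transducer gene htr18 was at 0.33 ± 0.10. The htr18 probe was above background on only 2 of the 4 dark arrays, and its value was 0.19 with no background correction, 0.78 with plain subtraction and 0.04 with the number series as a term. The mean of this list too turned sign without that array. The TCA cycle had 5 of 6 higher (mean 0.04), with mdh at 0.19, citZ at 0.14, sdhC at 0.05 and sucC at -0.18. The rhodopsin list had 2 of 5 higher (mean 0.01, median -0.04, with a camera direction of lower), with hop at 0.13, sop1 at -0.07, sop2 at 0.06 and htr1 at -0.05.

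In DNA repair 2 of 4 were higher in light (median -0.04, with a mean of 1.8e-04 and a camera direction of lower), with mutL at 0.22, uvrB at -0.15, uvrA at -0.13 and radB at 0.06. Cobalamin and heme synthesis had 3 of 6 higher (mean 0.02), with cbiQ at 0.09, hemA at 0.06, cbiG at 0.05 and cbiT at -0.02. Pyrimidine and purine synthesis had 4 of 9 higher (mean -0.02), with purF at 0.16, pyrB at 0.06, purL at -0.09 and pyrF at -0.38. Without the removed pyrF 4 of 8 were higher and the mean turned to 0.03, so the list has no direction of its own. With the number series as a term, the list means for light were 0.05 for chaperones and proteases, -0.01 for flagella and chemotaxis, -0.0075 for the TCA cycle, -0.01 for the rhodopsins, 0.14 for DNA repair, -0.06 for cobalamin and heme, and 0.0062 for pyrimidines and purines. Among the lists with under 3 named genes, bat was at -0.14, arcA at -0.10, arcC at -0.08, moaC at -0.25, moaA at 0.06, nuoL at -0.01, rpl12p at 0.09, msrA at -0.05, dpsA at -0.04 and phoU at 0.26.

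**Figure D2:**
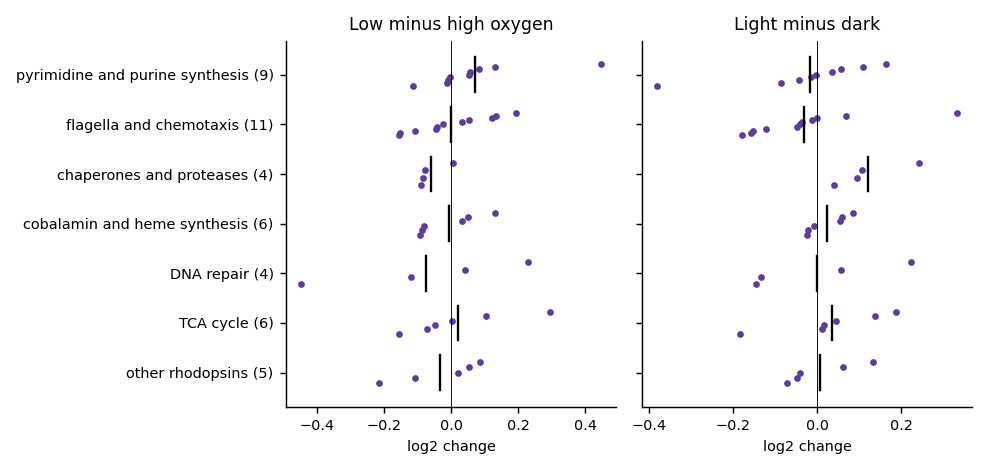
Log2 change (x axis) of each member (points) of the 7 tested gene lists (y axis, with the number of genes) for oxygen (left) and light (right), with a bar at the list mean. The points lie on both sides of 0 in each list except chaperones and proteases for light, where all 4 are above it.

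The changes differed between the dye orientations. For light, the arrays with the sample in Alexa 532 also compare the number series, so orientation and series cannot be told apart there. Across all probes, which are not independent replicates, the oxygen change on the arrays with the sample in Alexa 532 and that on the Alexa 647 arrays had a correlation of 0.02, and the light change one of -0.04. Among the 600 brightest probes the correlations were 0.13 and 0.05. The spread of the light change was 0.348 (SD over probes) on the Alexa 532 arrays and 0.183 on the Alexa 647 arrays, and that of the oxygen change 0.260 and 0.233. Among the named genes, infB differed between light and dark by 0.65 in the first orientation and 0.02 in the second, cysS by 0.64 and 0.19, and htr18 by 0.63 and 0.04. For purL the oxygen change was 0.44 and 0.46, and for cca the light change was 0.30 and 0.31.

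**Figure D3:**
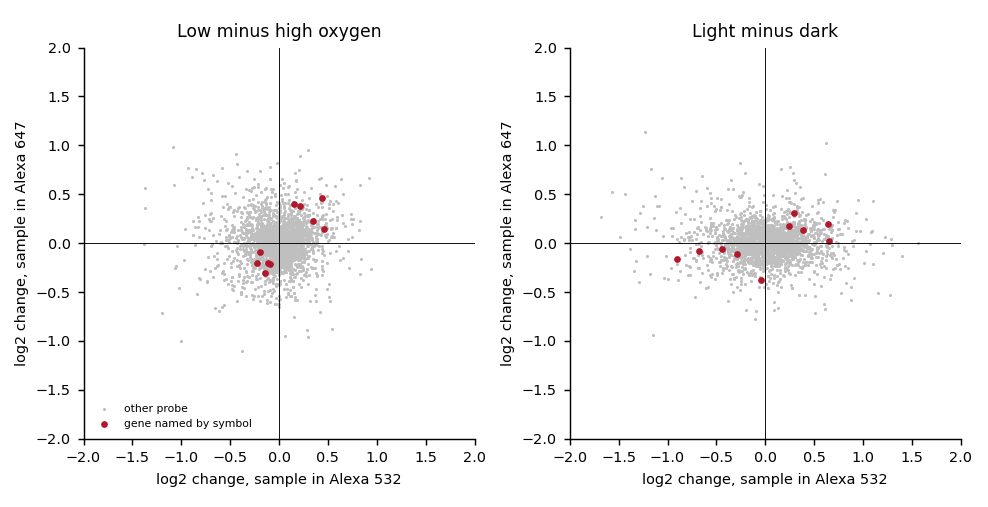
Log2 change of each of the 2400 probes on the arrays with the sample in Alexa 532 (x axis) and in Alexa 647 (y axis). Oxygen is on the left and light on the right. In red are the named genes with the largest changes in each direction and the same sign in all differences between single arrays. This choice gives each of them the same sign in both orientations, so the red points do not show how well the orientations match. The clouds show a correlation of 0.02 for oxygen and -0.04 for light, and the light cloud is wider along the Alexa 532 axis.

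The oxygen change was then compared between light and dark, with 1 RNA sample per combination and so no test. Among named genes with the same sign of this difference in both orientations, the oxygen change of hisB (histidine synthesis) was higher in light than in dark by 0.72, that of purB (adenylosuccinate lyase) by 0.64, hutG (histidine breakdown) by 0.56 and serB (phosphoserine phosphatase) by 0.49. The difference was -0.53 for hemL (heme synthesis), -0.48 for infB, -0.43 for gatA (a subunit of the amidotransferase that makes glutaminyl or asparaginyl tRNA) and -0.42 for aroC (chorismate synthase). On the Alexa 532 and the Alexa 647 arrays it was 1.24 and 0.20 for hisB, and -0.93 and -0.04 for infB. These sizes thus rest mostly on 1 orientation. It was 0.36 and 0.92 for purB, 0.58 and 0.55 for hutG, and 0.55 and 0.43 for serB. For hemL it was -0.40 and -0.66, for gatA -0.64 and -0.22, and for aroC -0.41 and -0.42. The transcript of hutG was above background on 2 of the 8 arrays and that of purB on 3. Of any probe, the largest differences were in probe_491 (1.26), probe_1243 (1.20), probe_2715 (1.13) and probe_151 (1.07), and in probe_2585 (-2.23), probe_849 (-1.69), probe_743 (-1.51) and probe_4441 (-1.45), the last 4 above background on no array and probe_491 and probe_151 on 1, so these 6 are no measured differences. In all, 22 probes differed at least 2-fold with the same sign in both orientations, 8 higher and 14 lower, 0 of them with a symbol, and all were absent when only probes above background on all arrays were kept. Of the sum of squares over probes, oxygen took 33.6%, light 40.6% and this difference 25.8%. Noise alone would give each of these contrasts an equal share, so the shares are not the part explained by oxygen or light. The order of oxygen and light turned with the dye, with 26.5% and 47.5% on the Alexa 532 arrays and 44.6% and 27.5% on the Alexa 647 arrays, which lie in 1 number series. Oxygen was above light under 7 of 21 settings, among them median centring (39.4% and 38.6%), and its share ranged from 24.7% to 44.6%, so no order is given.

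Against the standard reference, the knockout strain had higher levels of argH (argininosuccinate lyase, 0.34 ± 0.12), arcC (0.28 ± 0.07) and pan1 (a proteasome-activating ATPase, 0.27 ± 0.09) on all 8 arrays (SD over 4 RNA samples). Lower on all 8 were rpl12p (-0.74 ± 0.17), hemA (glutamyl-tRNA reductase of heme synthesis, -0.42 ± 0.09), rpmC (another protein of the large ribosomal subunit, -0.41 ± 0.06), gdhA2 (-0.29 ± 0.22) and thiL (thiamine monophosphate kinase, -0.28 ± 0.11). Each SD is over ratios averaged over both dye orientations, so it leaves out the difference between them. With the sample in Alexa 532, hemA ranged from -0.34 to -0.11, and on the flipped arrays from -0.75 to -0.58. For rpl12p these ranges were -0.67 to -0.39 and -1.22 to -0.69. In the other genes named here the ranges of the orientations overlapped. The reference is a standard culture and no control of these conditions, so the levels against it were not tested. In all, 243 probes had the same sign on all arrays, 123 higher and 120 lower, and 10 of them have a symbol. All arrays share 1 reference RNA, so these signs are not independent. At least 2-fold apart was 1 probe, the unnamed probe_4433, at -2.20 ± 0.32, with single arrays from -0.91 to -2.80. Its sample channel was above background on 4 of 8 arrays, and the mean was -1.56 with no background correction and -2.70 with plain subtraction, so it is no measured fold. The next lowest mean was -0.76. With a minimum of 1.5-fold the count was 12, and with arrays of Alexa 532 alone 19.

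The deletions could not be checked well on these arrays. The pyrF gene, removed by the labels, was at -0.31 ± 0.23 against the reference, lower on 6 arrays and higher on the 2 arrays of the second number series (0.0091 and 0.29). Its signal was above background on 3 of 8 arrays in the sample channel and on 2 in the reference channel, so this ratio says little on the deletion. No probe could be assigned to phr1.

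**Figure D4:**
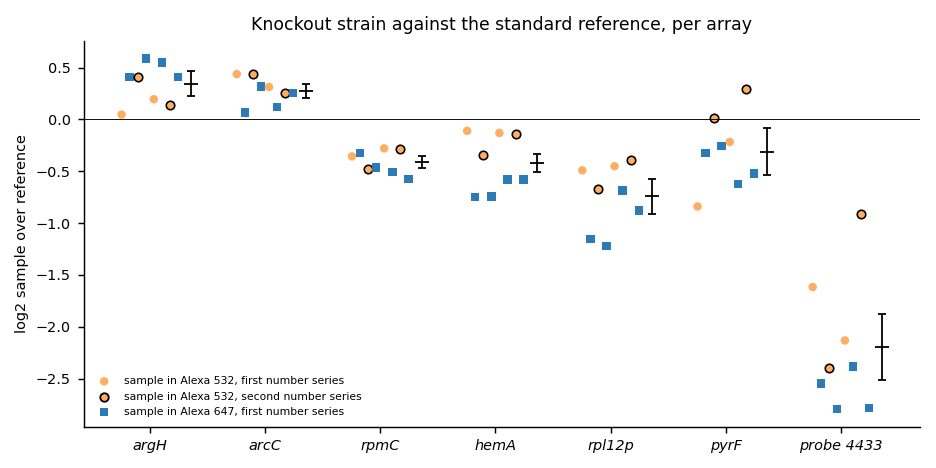
Log2 ratio of sample over reference (y axis) on each of the 8 arrays for 6 named genes and probe_4433 (x axis), with circles for the sample in Alexa 532, squares for Alexa 647, black outlines for the second number series, and the mean with its SD over 4 RNA samples. The ratios of probe_4433 lie from -2.80 to -0.91, and those of pyrF from -0.84 to 0.29.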

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

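All tests of explanations here were chosen after the results were seen. The 11 results that follow were singled out because a change had one direction on both arrays of one state and the opposite direction on both arrays of the other, and none of these differences was tested. Over all probes this held for the oxygen change of 222 (9.25%), where independent differences would give 12.5%.

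The oxygen change in light minus that in dark was 0.64 for purB, with 0.21 in light and -0.44 in dark. For serB it was 0.49, for icd 0.34 and for htr2 0.28. It was -0.42 for aroC, with -0.25 in light and 0.17 in dark, and -0.24 for phoU. Unnamed probes gave 1.26 (probe_491), 1.13 (probe_2715), -1.51 (probe_743) and -2.23 (probe_2585), of which probe_743 and probe_2585 were above background on no array, probe_491 on 1 and probe_2715 on 4 of 8. The purB probe was so on 3. For arcA the light change at high oxygen minus that at low oxygen was -0.34.

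The dye-flip arrays of an RNA sample gave unlike ratios, with correlations across probes of -0.31 to 0.10, against 0.35 to 0.75 between arrays of different RNA samples and the same dye. Noise of dim spots as the whole cause is argued against by the 600 brightest probes, where these correlations were -0.081 to 0.449, and a contribution of such noise stays open. A wrong dye label on an array is argued against by probe_4433, whose ratio stayed below 0 on all 8 arrays, with a highest value of -0.91. This rests on 1 probe, picked as the lowest against the reference. The value of -0.91 is from low_oxygen_dark replicate 1. There the net signal was 671 in the sample and 1211 in the reference channel. The sample was under the 95th percentile of the empty positions, at 893, and the label of that array is not decided. The sample signal was under that percentile also on high_oxygen_light replicate 1, high_oxygen_dark replicate 1 and low_oxygen_light replicate 2. Their ratios were further below 0 (-1.62, -2.40 and -2.38), with net reference signals of 1502, 3855 and 1047. A dye bias of single probes stays open, and the correlation of at least 0.557 between RNA samples in the difference between the orientations restates the pattern and decides nothing. No biological explanation was tested, as both arrays were taken to carry the same RNA, and the labels do not exclude separate cultures or extractions.

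The light change spread more over the probes on the arrays with the sample in Alexa 532, where light and dark also differ in array number series. Noise of dim spots as the whole cause is argued against by the 600 brightest probes, with a spread 1.68 times that of the Alexa 647 arrays. The dark Alexa 532 arrays, which form the second number series, had low signal over background. Their median spot read 2.69 and 2.14 times its background in Alexa 647, against 5.68 to 9.16 on the others. Their median background in that dye was 1830 and 1546, against 543 to 1012. The median spot itself was 5159 in high_oxygen_dark replicate 1 and 3433 in low_oxygen_dark replicate 1, against 4066 to 6517. Only low_oxygen_dark replicate 1 was thus also dim in that dye. Neighbouring spots had correlations of 0.538 and 0.487 on these arrays, against 0.559 to 0.698. A lower quality of these arrays stays open and cannot be told apart from the number series. The number series and a response of the cells to light cannot be told apart on the Alexa 532 arrays, where the light changes at high and at low oxygen had a correlation of 0.303, which both predict. The light changes of the orientations had a correlation of -0.037, and this decides nothing, since the light change on the Alexa 647 arrays did not repeat between oxygen levels (-0.0057).

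The unnamed probe_4433 was far below the reference on every array. A dye bias of the probe is argued against by the difference between the orientations divided by 2, at -0.43 against a mean of -2.20. Oxygen or light is argued against by the highest of the 4 RNA samples, at -1.85. A complete lack of RNA that binds the probe is argued against by 4 arrays with the sample channel above the 95th percentile of empty positions. That the probe belongs to a deleted gene and also binds other RNA may account for these values and was not tested, because the probe has no symbol.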

How the results depend on the processing

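Loess within sub-grids, the 6 arrays of the first series, the authors' table from spots blank on no array, the lists without pyrF and the adjustment over probes with a symbol were chosen after the data were seen; all other settings were fixed before. The count of probes for oxygen stayed at 0 under 24 of 29 settings and was 61 with median centring, 19 with the authors' table, 13 with its spots blank on no array, 62 with loess within sub-grids and 11 in the array-level fit with dye and block. The count for light stayed at 0 under 25 of 29 settings and was 38, 58, 47 and 62 under the first 4 of these. The estimated prior degrees of freedom were 19.2 with median centring, 40.4 within sub-grids and infinite with the authors' table, against 2.53 as reported and 3.25 in the array-level fit; the cause was not tested. Unadjusted counts ranged from 70 to 360 for oxygen and from 52 to 402 for light. The purL change kept its sign under 28 of 28 settings (0.39 to 0.55), gdhA2 under 25 of 27 and cca under 27 of 28 for oxygen. Some of these settings could not turn a sign. The array-level fits, the fit with no covariate and the other eBayes priors leave the oxygen values as they are by construction. These genes were picked for the same sign in all 4 differences. For oxygen this also fixes the sign within either dye orientation and within either number series. With the authors' table moaA was at -0.46 for light, opposite in sign to the reported 0.06; the sign also turned with median centring (-0.06), on the Alexa 532 arrays (-0.04) and without high_oxygen_light replicate 2 (-0.07), and the cause was not tested. Of 2938 gene values under other settings, 243 had the opposite sign with none past the threshold and 67 were past it. Gene lists passed under none of 20 settings, and 64 of 268 list shifts had the opposite sign. The estimated correlation is 1 of these settings and is no separate check.

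The reference comparison, 1 probe as reported, gave 12 at 1.5-fold, 4 with plain subtraction, 2 with median centring, 0 among probes above background, 2 with the authors' table, 7 on the Alexa 647 and 19 on the Alexa 532 arrays, and 1 to 2 without an array. The interaction count, 22 as reported, was 0 with no background correction, 80 with plain subtraction, 38 with an offset of 10, 0 among probes above background, 5 with the authors' table, 53 on the Alexa 647 and 140 on the Alexa 532 arrays, 8 within sub-grids and 54 to 130 without an array. The condition on both orientations cannot apply with a single orientation or a missing array, which by construction raises the count. The interaction share was 23.1% with no background correction, 29.1% with plain subtraction, 21.9% with median centring, 27.9% on the Alexa 647 arrays and 23.0% to 35.4% without an array, and the light share 26.4% to 50.6%. The cause of the other differences was not tested. The mean of pyrF ranged from -0.48 to -0.15; it is not above background, so that filter gives no value for it. Aquantile leaves ratios as they are by construction. Dim signal limits what these arrays show: 976 of 2400 probes were above background in both channels on all arrays.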

Other observations

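The added lists and their tests were chosen after the gene names were seen. Camera at the preset correlation called 0 of the 5 for oxygen (lowest adjusted p = 0.482, or 0.651 with an estimated correlation) and 0 for light (lowest adjusted p = 0.756, or 0.843), and 0 of their members passed over all probes or adjusted over the list alone. Of 12 aminoacyl-tRNA synthetase genes, which load tRNAs with their amino acids, 7 had higher values in light (mean 0.07), with cysS at 0.42, pheS at 0.15, serS at 0.14 and proS at 0.14. For oxygen 6 of the 12 were higher at low oxygen (mean 0.03), with cysS at 0.20, hisS at 0.15, serS at 0.14 and thrS at -0.13. In the glutamate and ammonium list 3 of 4 genes were higher at low oxygen (mean 0.13), with the glutamate dehydrogenase genes gdhA2, gdhA1 and gdhB at 0.29, 0.22 and -0.07 and glnA (glutamine synthetase) at 0.09. For light the mean was -0.06, with gdhA2 at -0.20, glnA at -0.09, gdhB at 0.04 and gdhA1 at 0.01.

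Histidine synthesis had 5 of 6 genes higher at low oxygen (mean 0.04), with hisA at -0.20, hisI at 0.16, hisD at 0.11 and hisF at 0.04, and 2 of 6 higher in light (mean -0.05), with hisB at -0.22, hisF at -0.17, hisA at 0.10 and hisD at 0.08. The genes of histidine breakdown were dim, with hutI above background on 0, hutU on 1 and hutG on 2 of the 8 arrays in the sample channel. Their mean was -0.12 for oxygen and 0.04 for light, which are no measured folds. In thiamine synthesis 2 of 3 were higher at low oxygen (mean 0.08), with thiD at 0.14, thiL at 0.12 and thiC at -0.02, and 1 of 3 in light (mean -0.0048), with thiL at 0.05, thiD at -0.04 and thiC at -0.03.

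With the number series as a term the means of the added lists for oxygen were the same. Within the first and the second series they were 0.06 and -0.05 for aminoacyl-tRNA synthetases, 0.09 and -0.09 for histidine synthesis, -0.14 and -0.03 for histidine breakdown, 0.11 and 0.20 for glutamate and ammonium, and 0.10 and 0.0032 for thiamine synthesis. For light, the means with this term and within the first series were 0.03, -0.08, 0.21, -0.07 and 0.05 in the same order, and the second series has no light array.

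Within arrays, neighbouring spots of a probe had correlations of 0.487 to 0.698, and the copies in the upper and lower parts of a slide 0.147 to 0.366. The oxygen changes of the upper and lower parts had a correlation of 0.21, and the light changes one of -0.06. Between RNA samples, ratios averaged over both orientations had correlations of 0.291 to 0.640 across probes.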
